A study of Macaca mulatta with 95 samples.

How the data were processed

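RNA of 95 single cells from rhesus macaque (Macaca mulatta) embryos grown in culture was sequenced, each cell as its own library. Per the labels' protocols, embryos were taken at 7 stages, from the 16-cell stage near day 3 to the hatched blastocyst near day 7, a membrane dye marked the outer cells before the embryo was taken apart, complementary DNA was poly(A)-tailed and amplified by PCR, and libraries were read as 100-base single-end reads. The protocols mention no molecular identifiers.

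The deposited table holds 1 value per gene symbol and cell and does not name its unit. The values were read as RPKM (reads per kilobase of gene and per megaread) made by the authors, since they are not whole, the totals per cell run from 557059 to 1000590, and the low values of a gene are whole multiples of a step that is the product of a gene factor and a cell factor. Per the submitters' processing notes, FastQC, TopHat2 version 2.1.0, HTSeq and DESeq2 were among the tools, with no role or order given. Neither the genome build, the annotation nor any filter on genes is stated in the sources used here, so no coordinates are given. Gene names are those of the table, and 14282 of its 16049 symbols are also in a RefSeq gene table of the rhesus macaque, which was used for names only. All 95 value columns were matched to a sample by title, and 0 columns were left over.

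Because the values are RPKM and not the raw counts that had been planned for, each group was summarised by the mean of the RPKM of its cells. The depth-weighted mean, which equals the planned sum of reads per group, was run as an alternative. Depth was read back from the steps of the values. For 10076 genes (62.8%), the values could be turned into whole reads within a tolerance of 0.05. Genes were kept for this because their values were whole, so the wholeness of the kept values is no separate check. The recovered reads are the reads of those genes alone and give a rough measure of depth. The relative depth from the cell factor, used as the weight, orders some cells otherwise. The cell HB_inner G-14 had 13.3 megareads recovered at a relative depth of 1.02, and MB_outer B-06 9.53 megareads at 1.24.

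No label names an animal, an embryo or a culture, so cells are not replicates and each group counts as 1 sample. None of the comparisons carries a test across genes or cells, and each difference describes these cells. The SD given beside a mean is the spread from cell to cell. For each comparison the log2 ratio of the group means was taken after adding 1 RPKM to each. A gene counted as measured at a mean of 5 RPKM or more on either side, and as higher or lower at a difference of at least 2-fold. The morula comparison gave the 3 stages equal weight. For each gene list fixed before the data were examined, the members higher, lower and between were counted, and the list's median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these cells. Shares of cells carry exact binomial (Clopper-Pearson) intervals at the 95% level. These cover counting error only, since cells of the same embryo are not independent.

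Cell titles begin with 1 of 5 letters (A, B, D, G and H) that the labels do not explain. A letter can stand for a batch, an embryo or a collection day, so list counts within letters are given beside the pooled ones for the cluster comparisons, and for part of the lists for outer against inner cells. For 9 cells the title and stage label say late blastocyst and the source name says hatched blastocyst. These were kept as late blastocyst, and the alternatives left them out or moved them.

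The 70 blastocyst cells were clustered on log2(RPKM + 1) of the 1000 most variable genes among 7747 with at least 10 RPKM in at least 5 cells. Members of the lists that were not markers were left out, and Ward clustering on 10 principal components gave 5 clusters. A cluster was named after a lineage where at least 50% of the lineage's markers, and no fewer than 3, lay 1 or more log2 units above the other cells, and where the 10 genes of largest fold held at least 1 of its markers and no more markers of another lineage. Otherwise it keeps a number. No early or middle blastocyst cell fell in the epiblast-like cluster, so the planned comparison of late with early epiblast-like cells could not be made. Its early side was replaced, after the data were seen, by the unnamed cluster that holds most inner early and middle blastocyst cells of letters G and H.

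Lists read were trophectoderm, epiblast and hypoblast markers, Hippo and polarity genes, junction and transport genes, naive and primed pluripotency, amnion and gastrulation, oocyte (maternal), genome activation, Nodal, FGF, WNT, LIF, BMP, DNA methylation, glycolysis, oxidative phosphorylation, extracellular matrix, lipoprotein secretion, G2/M and stress genes, and markers of cumulus, fibroblast, blood and sperm cells. The genes named were chosen by a rule set before the data were examined. It takes up to 4 members of each list with the largest differences, and the 8 highest and 8 lowest of all genes with at least 20 RPKM on the higher side. These had to be above 0 in at least 75% of that side's cells, at least 2-fold apart in the same direction by mean, by depth-weighted mean and by median, and to keep that direction within each title letter that has at least 2 cells on both sides. Some genes that the rule names are not reported here. Ribosomal protein genes, mitochondrial genes and symbols without a gene name were left out. Genes used in the clustering and lineage markers were also left out of the second part where clusters were compared. The rule also names 11 lineage genes at every stage, of which GATA6 is not among the symbols used here.

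Alternatives were other scalings (median-of-ratios size factors over genes above 0 in at least 50% of cells, or over the 1159 genes above 0 in all cells), other filters, sizes and pseudocounts, other cluster settings, single title letters, and leaving out each cell of groups of 2 to 5 cells. TMM scaling was planned on counts and was not run. The planned filter of 100000 counts or 2000 genes would remove no cell.

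The steps were tested on simulated data. With 200 of 6230 genes set 4-fold apart and the cell-to-cell spread of the letter H hatched blastocyst cells, 98.0% of the higher and 98.1% of the lower genes passed 2-fold for 16 against 16 cells, and 6.58% of the unchanged genes did. For 11 against 22 cells, 97.8% and 98.2% passed, and 7.56% of the unchanged genes. For 16 against 4 cells, 95.9% and 91.2% passed, and 19.0% of the unchanged genes. For 5 against 5 cells these shares were 92.5%, 92.0% and 22.9%, so a difference of 2-fold between groups this small is common with no difference present. All simulated cells had the spread of 1 title letter, stage and cluster, whereas the real groups mix them. At every group size these shares are thus no error rates of the real comparisons. Planted classes were given back for 100% of the simulated cells over 16049 genes. The classes were of equal size, with strongly raised markers, the true number of clusters and no letter difference. This checks the code and does not bear on the clusters of the real cells. Read recovery was exact in all cells for 99.96% of 9931 genes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.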

Results

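Expression of 16049 genes was measured in 95 single cells of rhesus macaque embryos cultured to the blastocyst. The 16-cell stage (day 3) gave 3 outer and 2 inner cells, the early morula (day 4) and the late morula (day 4.5) each 5 outer and 5 inner cells. The early blastocyst (day 5), which has a small cavity, gave 6 outer and 10 inner cells, and the middle blastocyst (day 5.5) 5 outer and 12 inner cells. The late blastocyst (day 6) gave 19 and the hatched blastocyst (day 7) 18 cells, all inner. The recovered reads per cell ran from 1.40 to 13.3 megareads with a median of 7.48 megareads, and 9 cells had fewer than 4 megareads. The median was lowest in the late morula, at 2.66 megareads in outer and 3.79 megareads in inner cells. Between 2358 and 7379 genes per cell reached 1 RPKM, with a median of 4634. ACTB, GAPDH, EEF1A1, TPT1 and EEF2 were above 0 in all 95 cells.

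Stage, position and title letter overlap in part. The 16-cell cells carry letter B, early morula H, late morula D, outer early blastocyst A and outer middle blastocyst B, while the inner blastocyst cells spread over A, B, G and H. The median number of genes at 1 RPKM or more was 3279 in letter A, 3893 in B, 3719.5 in D, 4711 in G and 6034 in H. Several subunits of the respiratory chain followed the letter. COX6C averaged 7.34 RPKM (SD over cells 8.32) in the 9 inner early and middle blastocyst cells of letters A and B and 469 (517) in the 13 of letters G and H. NDUFA1 averaged 11.3 against 570.6 and COX7C 45.7 against 1450.1, while UQCRC1 stood at 2040.2 against 569. The same genes split the earlier stages, with COX6C at 13.3 in 16-cell (B), 210.8 in early morula (H) and 4.94 in late morula (D).

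**Figure D1:**
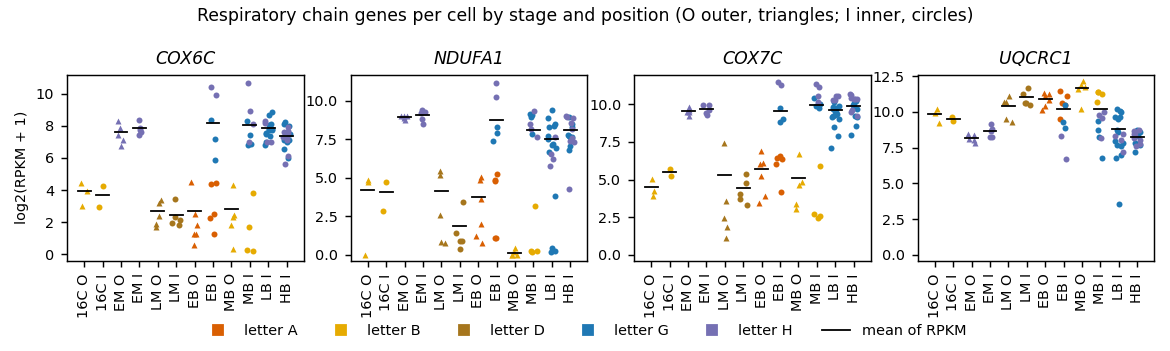
COX6C, NDUFA1, COX7C and UQCRC1 in each cell as log2(RPKM + 1), by stage and position, coloured by title letter, with a line at the log2 of the mean RPKM plus 1. Cells of letters G and H lie mostly above cells of letters A, B and D for COX6C, NDUFA1 and COX7C, within the early and middle blastocyst as well as between stages, and mostly below them for UQCRC1.

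Lineage genes were first followed through all stages. POU5F1, a gene of pluripotent cells, was present from the 16-cell stage on, at 4604 RPKM (SD 1384) in outer and 4901 (1104) in inner cells. SOX17, a gene of the hypoblast, averaged at most 0.0955 RPKM in every group up to the late morula, and 44.5 (79.9) in outer and 116 (330) in inner early blastocyst cells. The inner mean rests on the cell EB_inner A-08 at 1050.6 RPKM, without which it is 12.7 (31.8), and inner cells of letters G and H averaged 4.16 and 0.0122. Without the cell EB_outer A-06 the outer mean is 12.6 (17.7). KRT18, a keratin of epithelial cells, stood at 11041 (3837) in outer early blastocyst cells, each of them above every inner cell of the stage, which averaged 1265 (1407). Inner cells of the same letter as the outer ones averaged 2193 (1475). At the middle blastocyst KRT18 stood at 12336 (10904) in outer cells and at 11688 (4986) in inner cells of the same letter, against 781 (560) in inner cells of letter G and 416 (594) of letter H. PDGFRA stayed low, with its highest mean, 2.90 (6.21), in outer middle blastocyst cells, or 0.129 (0.258) without the cell MB_outer B-02. In hatched blastocysts NANOG averaged 628 (251) in the 9 cells of letter H and 0.457 (0.448) in the 9 of letter G, and GATA2 1.52 (4.39) against 445.8 (245).

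**Figure D2:**
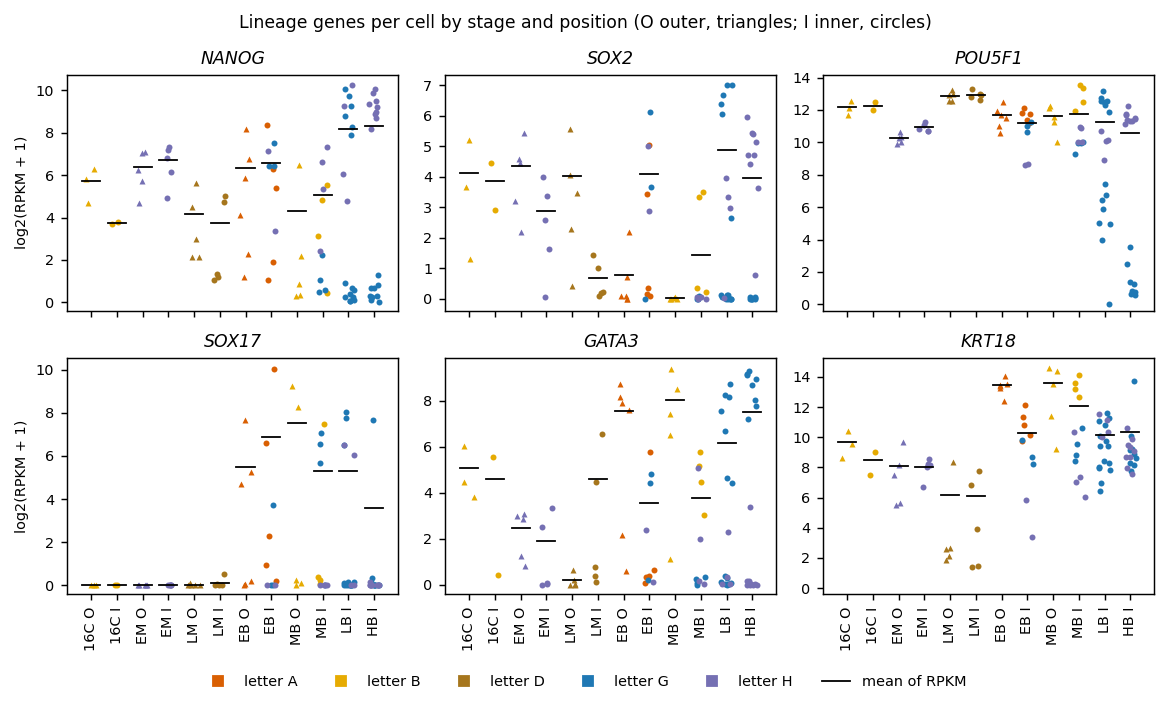
NANOG, SOX2, POU5F1, SOX17, GATA3 and KRT18 in each of the 95 cells as log2(RPKM + 1), by stage and position, coloured by title letter, with a line at the log2 of the mean RPKM plus 1. GATA3 has a higher mean in outer than in inner cells of the early and middle blastocyst, while KRT18 in inner middle blastocyst cells of letter B lies near the outer cells, and NANOG and POU5F1 split the late and hatched blastocyst cells into a high and a low set.

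The first comparison asks how position separates lineage genes once a cavity has formed. Outer cells of early and middle blastocysts held more RNA of trophectoderm genes, the lineage that forms the embryo's outer layer, than inner cells. GATA3 averaged 220.1 RPKM (SD 207) in 11 outer and 11.9 (17.8) in 22 inner cells, and GATA2 66.1 (78.8) against 3.44 (8.82). PTGES was higher in outer cells by 4.18 log2 units. Among genes of pluripotent epiblast cells NODAL (-4.20 log2 units), GDF3 (-3.26) and SOX2 (-2.72) were lower in outer cells. Of 14 measured trophectoderm markers 10 were at least 2-fold higher and 0 lower in outer cells, with the list's median of 1.82 at percentile 100 of random lists. Of 10 epiblast markers 0 were higher and 3 lower, with a median of -0.64 at percentile 25.2, beside an all-gene median of -0.40. With only inner cells of the outer cells' letters, 7 of 14 trophectoderm markers were higher and 3 lower, at percentile 99.9, and 0 of 10 epiblast markers were higher and 4 lower, at percentile 2.84. The trophectoderm markers were higher against lower by 6 to 2 within letter A at the early and by 9 to 2 within letter B at the middle blastocyst, each over 13 measured, and the epiblast markers by 1 to 4 and by 0 to 8, each over 10.

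Hypoblast and junction genes depended on the letters compared at the blastocyst. Of 12 hypoblast markers 4 were higher in outer cells and 1 lower. LAMA1 was higher by 2.56, LRP2 by 2.34 and COL4A2 by 1.40 log2 units, and COL4A1 stood at -1.35. LAMA1 rests on the cell MB_outer B-01, without which it stood at -0.26. Within letter B at the middle blastocyst, 11 of 12 hypoblast markers were higher in the 5 outer cells than in the 4 inner ones, but 7 of 11 without the cell MB_outer B-01 and 6 of 9 without MB_outer B-03. Within letter A at the early blastocyst 5 of 11 were higher and 4 lower (percentile 37.3). CLDN3 (3.48) and AQP11 (3.08), genes of tight junctions and water transport, were higher in outer cells, while DSC2 (-2.36) and ATP1B1 (-2.22) were lower. Of 15 junction and transport genes 3 were higher and 6 lower, against 5 higher and 2 lower of 13 with matched letters, 6 to 3 of 14 within letter A and 8 to 2 of 13 within letter B (percentiles 93.4 and 99.8). Of 9 Hippo and polarity genes 0 were higher and 4 lower, with WWTR1 at -4.05, SAV1 at -2.76, AMOT at -2.46 and YAP1 at -2.42, but with matched letters 0 of 6 were past 2-fold in either direction and AMOT (0.20) and SAV1 (0.03) changed sign. Over all 6485 measured genes 1219 were higher and 2530 lower, so the pooled counts of lower Hippo and junction genes lie near those of any genes. Their list medians of 0.13 and -0.72 stood at percentiles 81.0 and 15.3 of random lists.

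Over all genes, the largest differences with the same direction within letters A and B were as follows. ZFP36 averaged 221.8 RPKM (SD 368) in outer and 4.18 (11.5) in inner cells, CTSE 35.0 (60.4) against 0.0309 (0.0553), RHOV 61.7 (103) against 1.02 (3.36), TSPAN15 175 (254) against 4.99 (15.8) and HRAS 167 (233) against 7.10 (12.5), followed by GATA3 and GATA2. Lower in outer cells were SNRPE (-6.03 log2 units), PHLDA3 (-6.03), ATP5J (-6.01), TMEM92 (-5.88), GLRX3 (-5.78), NDUFA1 (-5.44), SPSB2 (-5.38) and RPA3 (-5.34). All outer cells carry letters A and B and 13 of the 22 inner cells carry G and H, so the size of these values holds the letter difference as well. Median-of-ratios size factors gave splits of higher to lower of 3 to 3 for epiblast, 8 to 2 for hypoblast, 7 to 2 for Hippo and 6 to 1 for junction genes, with ATP1B1 at 0.31, and factors over genes above 0 in all cells gave 3 to 3 for Hippo and 5 to 4 for junction genes.

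The next comparison asks whether position already separates these genes before the cavity forms. Between 13 outer and 12 inner cells of the 16-cell stage and the morulae, 5 lineage markers differed by 2-fold, in both directions. Among genes of cell contacts CLDN4 averaged 64.1 RPKM (SD 175) in outer and 630.0 (971) in inner cells, CLDN3 2.92 (2.99) against 18.9 (19.2) and CDH1 8.17 (7.48) against 23.5 (24.6), while ATP1B3, a subunit of the sodium pump, was higher by 1.02 log2 units. Of 11 junction and transport genes 1 was higher and 3 lower, with the list's median of -0.38 at percentile 3.33. SOX2 was higher in outer cells by 1.21 log2 units and NODAL stood at -2.66, which makes 1 of 6 epiblast markers higher and 1 lower. Of 7 trophectoderm markers KRT19 (1.76) and DAB2 (1.14) were higher and PGF (-2.46) lower, but KRT19 stood at -0.36 without the cell 16C_outer B-01. Only HNF4A (-0.32) was measured of the hypoblast markers, and 0 of 10 Hippo and polarity genes were past 2-fold over the 3 stages together.

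By stage, the trophectoderm markers were higher to lower by 4 to 0 of 7 at the 16-cell stage, 0 to 0 of 5 in the early and 3 to 3 of 7 in the late morula, and the junction and transport genes by 2 to 2 of 8, 1 to 4 of 14 and 3 to 4 of 10. Hippo and polarity genes differed in direction between stages, with 0 to 3 of 8, 2 to 0 of 11 and 2 to 1 of 6. CLDN4 stood at 0.12 log2 units at the 16-cell stage and CDH1 at -0.20 in the early morula. Over all genes, those with the largest differences in the same direction at all 3 stages were CCDC19 (4.32 log2 units), GNMT (3.94), TEX264 (3.77), FAH (2.86), PMM1 (2.83), USE1 (2.80) and POP1 (2.79), higher in outer cells. PYCR1 (-3.52), RNASET2 (-3.20), TLCD1 (-3.04), UBAC2 (-2.65), TOR2A (-2.59), C17orf70 (-2.54), BLOC1S4 (-2.51) and TSC22D4 (-2.41) were lower. In simulated groups of 5 against 5 cells 22.9% of unchanged genes passed 2-fold. The simulated spread was that of letter H hatched blastocyst cells, not of cells of these stages. Over all measured genes 1246 of 5194 were higher and 1071 lower at the 16-cell stage. The counts were 1061 and 600 of 6576 in the early and 1517 and 1309 of 4868 in the late morula. Median-of-ratios size factors gave splits of 3 to 3 for trophectoderm, 1 to 0 for epiblast and 1 to 1 for Hippo genes, and factors over genes above 0 in all cells 1 to 0 for Hippo genes.

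The third comparison follows the cells from the 16-cell stage, when maternal RNA is still present, to the late morula. Maternal and early embryonic genes were lower in the 10 late morula cells than in the 5 cells of the 16-cell stage. TLE6, a gene of the oocyte's maternal complex, averaged 1.41 RPKM (SD 4.44) against 124 (110), and ZP3 0.145 (0.203) against 9.41 (17.0), while ZP4 and ZAR1L were listed at 0 in the late morula. DUXA, a factor of genome activation, averaged 0.147 (0.169) against 19.8 (15.0), with ZNF280A at -3.08, H3F3C at -2.62 and DPRX at -2.34 log2 units. CDKN1A, an inhibitor of the cell cycle, stood at 213 (197) in the late morula and at 0.0107 (0.0240) at the 16-cell stage. Of 8 oocyte genes 0 were higher and 6 lower (percentile 0.110), or 3 lower without the cell 16C_inner B-01. Of 7 genome activation genes 1 was higher and 5 lower (percentile 0.170), and of 12 stress genes 6 were higher and 2 lower (percentile 99.1). The stress and G2/M lists were fixed beforehand but were not planned for this comparison.

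The cell cycle differed too. CCNB1, a cyclin of mitosis, averaged 1.04 RPKM in late morula cells and 54.4 (SD 23.2) at the 16-cell stage, and of 10 G2/M genes 0 were higher and 6 lower, with AURKB at -2.50, AURKA at -1.78 and CDC20 at -1.57. Among stress genes PMAIP1 (2.38) and GADD45A (2.31) were higher and FOS (-3.91) lower. CLDN4 (4.94), CLDN3 (2.44) and TJP1 (1.92) were higher in the late morula and AQP3 (-3.84) lower, with 5 of 10 junction and transport genes higher and 1 lower. Of 19 naive pluripotency genes TBX3 (3.11) was higher and 6 were lower, with ARGFX at -3.27, TFCP2L1 at -2.42 and ZFP42 at -2.39. Of 15 glycolysis genes 3 were higher and 6 lower, with PFKL at 4.25, HK2 at 3.93, TPI1 at -2.21 and ENO1 at -1.98. Of 20 oxidative phosphorylation genes 3 were higher and 7 lower, with SDHC at -3.03, COX5A at 1.64, NDUFS5 at -1.58 and SDHA at -1.48. Over all 5297 measured genes 1241 were higher and 1723 lower. The counts of lower naive, glycolysis and oxidative phosphorylation genes thus lie near those of any genes. Their list medians stood at percentiles 13.3, 2.26 and 6.16 of random lists.

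Over all genes, GDF15 (8.58 log2 units), PHLDA3 (8.37), CHAC1 (7.88), CDKN1A (7.73), TYROBP (6.28), EIF4E (6.24), SLC25A22 (6.04) and AGTRAP (6.02) were highest in the late morula. GIP (-7.13), DMRTB1 (-7.05), TEX19 (-6.89), TTC9B (-6.55), LGALS7 (-6.14), S100A16 (-6.08), ENO2 (-6.07) and ALOX12B (-5.97) were lowest. The early morula did not lie between these stages for every list. Oocyte genes were higher to lower by 1 to 6 of 9 in early morula against 16-cell cells, but genome activation genes by 2 to 2 of 8, G2/M genes by 8 to 3 of 15, oxidative phosphorylation genes by 12 to 1 of 22 and stress genes by 3 to 5 of 12. Stage and title letter (B, H, D) cannot be told apart here, and late morula cells have the lowest median depth. Median-of-ratios size factors gave splits of 2 to 3 for genome activation, 8 to 1 for junction and transport, 9 to 1 for naive, 7 to 1 for glycolysis, 11 to 1 for oxidative phosphorylation, with SDHA at 0.39, 5 to 1 for G2/M, with CDC20 at 0.02, and 9 to 1 for stress genes, whereas factors over genes above 0 in all cells gave 5 to 7 for oxidative phosphorylation, 0 to 5 of 7 for oocyte and 1 to 5 of 18 for naive genes.

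Clustering the 70 blastocyst cells gave 3 clusters with a lineage and 2 without. The trophectoderm-like cluster held 13 inner cells, 8 hatched and 5 late blastocyst, with 12 trophectoderm markers above the other cells. The epiblast-like cluster held 16 cells, 7 late blastocyst cells of letter G and 9 hatched blastocyst cells of letter H, with 9 epiblast markers above. The hypoblast-like cluster held 4 cells, 3 late and 1 hatched, with 15 hypoblast markers above. Of 19 late blastocyst cells 36.8% (95% interval 16.3 to 61.6) were epiblast-like, 26.3% (9.15 to 51.2) trophectoderm-like, 15.8% (3.38 to 39.6) hypoblast-like and 21.1% (6.05 to 45.6) in cluster 5. Of 18 hatched blastocyst cells 50.0% (26.0 to 74.0) were epiblast-like, 44.4% (21.5 to 69.2) trophectoderm-like and 5.56% (0.141 to 27.3) hypoblast-like.

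The clusters follow the title letters closely. All 20 early and middle blastocyst cells of letters A and B, outer and inner, fell in cluster 1 with 1 cell of letter H, and none of the 3 named clusters held an early or middle blastocyst cell. Cluster 5, called the early cluster below, held 5 early and 7 middle blastocyst cells of letters G and H, and the 4 late blastocyst cells of letter H. In cluster 5, 5 hypoblast markers and 1 epiblast marker lay above the other cells, so it was not named epiblast-like. It is not uniform, since GATA4 averaged 122 RPKM (SD 18.0) and NANOG 1.41 (1.55) in its 4 middle blastocyst cells of letter G. In hatched blastocysts 8 of 9 cells of letter G were trophectoderm-like (88.9%, 51.8 to 99.7) and 9 of 9 of letter H epiblast-like, so the shares of a stage depend on how many cells of each letter were sequenced. The 5 trophectoderm-like late blastocyst cells are all among the 9 with conflicting stage labels, and without those 9 the late blastocyst held 0 trophectoderm-like and 7 epiblast-like cells.

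**Figure D3:**
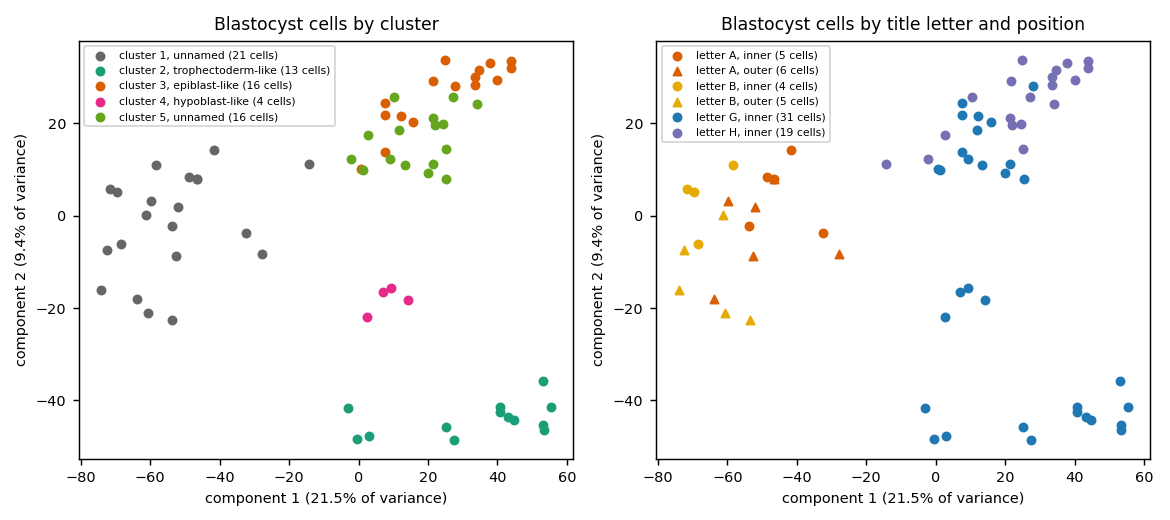
The 70 blastocyst cells on principal components 1 and 2 (21.5% and 9.43% of the variance), coloured by cluster on the left and by title letter on the right, with outer cells as triangles. Cells of letters A and B lie apart from cells of letters G and H along component 1, and the 13 trophectoderm-like cells lie low on component 2.

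The series title names naive and primed pluripotency, states of epiblast cells before and after implantation, so the 16 epiblast-like cells were compared with the 16 cells of the early cluster. Late epiblast-like cells held more RNA of several primed genes and less of several naive ones. The naive list as a whole did not stand out from random lists. ZIC2, a factor of primed cells, averaged 112 RPKM (SD 116) against 0.0603 (0.0806), and was above 0 in 15 and 10 cells. ETV5 was higher by 4.00, PTPRZ1 by 3.96 and SFRP2 by 3.27 log2 units, but DUSP6 (-6.22), CDH2 (-3.63) and OTX2 were lower. The naive factor KLF4 averaged 68.4 (62.1) against 467 (313), with ARGFX at -3.79, TBX3 at -3.29, TFCP2L1 at -2.15 and KLF5 at -1.54, whereas the naive genes KHDC3L (2.33) and DPPA5 were higher. Of 17 primed genes 11 were higher and 5 lower, with the list's median of 1.87 at percentile 100. Of 16 naive genes 2 were higher and 7 lower, with a median of -0.28 at percentile 22.7. Within letter G (7 against 7 cells) the primed genes were higher to lower by 10 to 3 and the naive ones by 3 to 5, and within letter H (9 against 9) by 10 to 4 and 1 to 7. The naive medians stood at percentiles 46.9 in letter G and 20.3 in letter H, the primed ones at 100 in both. Over all measured genes 1353 of 6878 were higher and 2260 lower in letter G, and 1615 and 1310 of 7075 in letter H. The naive counts in letter G thus lie near those of any genes. The early side of letter G includes the 4 middle blastocyst cells with GATA4 at 122 RPKM, and without these 4 the pooled counts were 10 primed genes higher and 7 naive genes lower. The early side of letter H includes 4 late blastocyst cells with conflicting labels. The epiblast-like cells are late blastocyst in letter G and hatched blastocyst in letter H, so the letters also differ in stage.

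**Figure D4:**
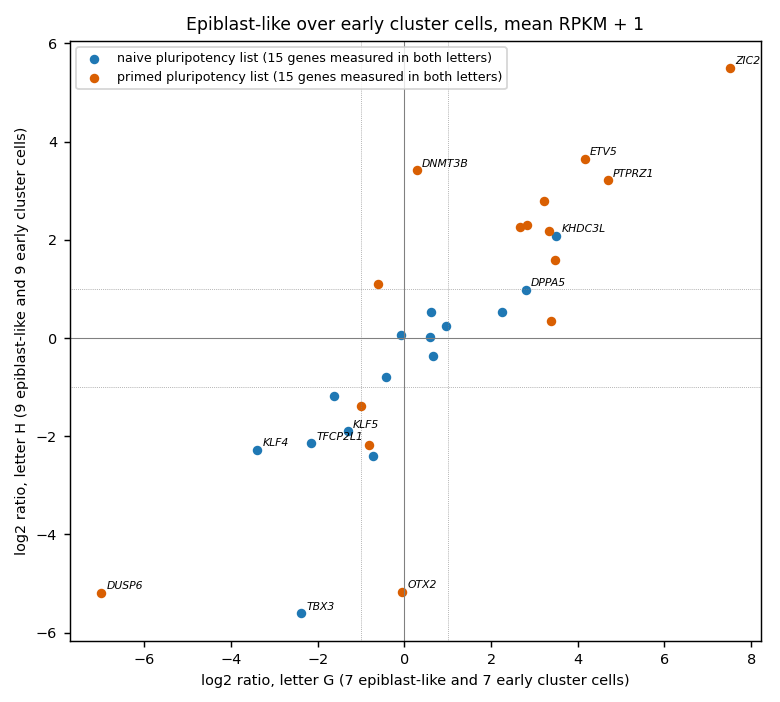
Log2 ratios of epiblast-like over early cluster cells for naive and primed genes measured in both letters, with letter G on the horizontal and letter H on the vertical axis. ZIC2, ETV5 and PTPRZ1 are higher and KLF4, TBX3 and TFCP2L1 lower in both letters, while DNMT3B is near 0 in letter G (0.28) and at 3.42 in letter H.

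Signalling genes differed between these clusters as well. The Nodal, BMP and WNT lists stood out from random lists in letter G but not in letter H. Over all 6959 measured genes of both letters 1107 were higher and 1273 lower. LEFTY2 (4.56), NODAL (3.51), GDF3 (3.44) and SMAD7 (3.00) were higher in epiblast-like cells, with 6 of 13 Nodal genes higher and 2 lower, though LEFTY2, NODAL and GDF3 also serve as epiblast markers. The BMP targets ID1 (5.15) and ID2 (4.00) were higher, and of 11 BMP genes 4 were higher and 3 lower. Of 10 WNT genes 5 were higher and 1 lower, with SP5 at 5.52 RPKM (14.1) against 0.00464 (0.0129) and log2 ratios of TCF7L1 at 2.57 and FZD7 at 2.50. Of 7 LIF pathway genes 0 were higher and 3 lower, with IL6R at -3.84, SOCS3 at -2.76 and IL6ST at -1.93. Of 10 FGF genes 3 were higher and 4 lower, with FGFR2 at -2.81 and ETV4, a marker, at 2.30. Of 6 amnion and gastrulation genes 3 were higher and 3 lower. T (6.28), BMP4 (2.96) and EOMES (2.34) were higher and GSC (-4.88) lower, but within letter G BMP4 stood at -0.05 and within letter H EOMES at -2.31. The amnion and gastrulation list went opposite ways in the letters, with 5 to 2 of 7 and a median of 3.00 in letter G and 2 to 3 of 5 and -1.74 in letter H. The letters differ in stage here, as the epiblast-like cells are late blastocyst in letter G and hatched blastocyst in letter H. In letter H, 4 early cluster cells are late blastocyst cells with conflicting labels. Against the 5 others their list medians were 2.44 for amnion and gastrulation, 1.39 for Nodal and 1.70 for FGF genes. They were 1.17 for BMP, 0.10 for WNT and -0.53 for LIF genes. Letter and stage cannot be told apart in these splits. In letters G and H, higher to lower, the Nodal genes stood at 6 to 2 of 12 and 6 to 3 of 13, BMP at 5 to 3 of 9 and 4 to 3 of 8, WNT at 8 to 1 of 10 and 3 to 1 of 8, LIF at 0 to 3 and 0 to 2 of 6, and FGF at 5 to 4 of 12 and 4 to 3 of 9. The list medians in G and H stood at percentiles 99.84 and 52.0 for Nodal, 99.81 and 75.7 for BMP, and 99.98 and 43.8 for WNT. They stood at 3.07 and 2.22 for LIF and at 88.95 and 98.0 for FGF genes. Over both letters LIF stood at percentile 9.46.

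DNA methylation and metabolism completed the planned lists. DNMT1 was higher in epiblast-like cells by 2.42 and DNMT3B by 1.58 log2 units, with 2 of 6 DNA methylation genes higher and 0 lower. LDHA (-3.06) and SLC2A1 (-2.78), which serve lactate and glucose transport and turnover, were lower and PFKM (2.21) and PDK1 (1.48) higher, with 3 of 18 glycolysis genes higher and 4 lower. Of 22 oxidative phosphorylation genes 0 were higher and 4 lower, with NDUFA4 at -1.25, UQCRQ at -1.15, NDUFB3 at -1.14 and COX6C at -1.11, the last at 0.49 within letter G. That count of lower genes lies near that of any genes (1273 of 6959). The list's median of -0.61 stood at percentile 0.53 of random lists, and the medians within letters G and H at 33.0 and 0.4. In letters G and H, higher to lower, oxidative phosphorylation genes stood at 0 to 2 and 0 to 8 of 22, glycolysis at 2 to 3 of 18 and 2 to 4 of 16, and DNA methylation at 2 to 1 of 8 and 3 to 0 of 6. Over all genes outside the clustering, ZIC2 (6.73), CMBL (5.19), UCHL1 (4.73), IGFBP4 (4.70), DPYSL3 (4.69), FBLIM1 (4.51), DMRTB1 (4.41) and SLC39A14 (4.14) were highest. CLDN4 (-7.84), DUSP6, GADD45A (-5.71), ZNF280A (-5.12), GSC, CLDN3 (-4.73) and FOSL2 (-4.67) were lowest. Median-of-ratios size factors gave splits of 6 to 1 for Nodal, 5 to 2 for FGF and WNT and 4 to 2 for glycolysis genes, and factors over genes above 0 in all cells 3 to 2 for glycolysis genes.

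The last comparison sets the 16 epiblast-like cells against the 4 hypoblast-like cells, the lineages that part within the inner cell mass. Hypoblast-like cells held far more RNA of basement membrane and secretory genes. FN1 averaged 9.92 RPKM (SD 10.4) in epiblast-like and 1521 (995) in hypoblast-like cells, and the transport protein TTR 0.0182 (0.0432) against 180 (187). Of 12 extracellular matrix genes 0 were higher and 11 lower in epiblast-like cells, and of 7 lipoprotein genes 0 were higher and 7 lower, each list at percentile 0 of random lists. These counts are partly fixed by the naming of the cluster, since NID2 (-9.85), COL4A1 (-6.52), LAMA1 (-6.44), COL4A2, LAMB1 and APOA1 (-11.06) are among them and also serve as hypoblast markers. Without these markers 0 of 7 matrix genes were higher and 6 lower, and 0 of 6 lipoprotein genes were higher and 6 lower, at percentiles 0.0400 and 0. APOM stood at -6.23 and MTTP at -6.01, or at -4.06 and -4.19 without the cell HB_inner G-14. The counts with markers held within letter G, where 7 epiblast-like cells were compared with the 4.

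WNT, BMP and Nodal genes were more often lower than higher in epiblast-like cells against hypoblast-like ones, which for BMP genes rests on 1 cell. Without the cell HB_inner G-14, 5 of 12 BMP genes were higher and 4 lower, 4 of 10 FGF genes higher and 2 lower, and 3 of 6 LIF pathway genes higher and 1 lower. With any 1 of the 4 left out, 8 to 10 WNT and 6 to 7 Nodal genes were lower, and the higher ones were 2 Nodal genes without LB_inner G-12 and 4 BMP genes without LB_inner G-17. The WNT antagonist DKK1 averaged 7.49 RPKM (20.4) against 1074 (1917), and WNT11 stood at -5.76, RSPO3, a marker, at -4.60 and SFRP1 at -3.56, with 2 of 14 WNT genes higher and 10 lower. Without the cell LB_inner G-11 the 3 other hypoblast-like cells averaged 119 RPKM (206) of DKK1, a log2 ratio of -3.82. SFRP1 stood at 1.90 without the cell LB_inner G-17, and RSPO3 at -1.15 without HB_inner G-14. The phosphatase gene DUSP6 stood at -7.62, EGR1 at -5.02 and SPRED1 at -3.62, and FGF4, a marker, was listed at 0 in hypoblast-like cells, with 4 of 12 FGF genes higher and 6 lower. Without the cell HB_inner G-14, EGR1 stood at -0.96, below 2-fold, and DUSP6 at -4.31, and without LB_inner G-17 SPRED1 stood at -2.77. Of 12 Nodal genes 4 were higher and 7 lower, with LEFTY2 at -4.27, LEFTY1 at -3.15 and NODAL at -2.44. LEFTY1 stood at -1.87 and NODAL at -1.51 without the cell HB_inner G-14, and LEFTY2 at -3.62 without LB_inner G-17. Of 13 BMP genes 2 were higher and 8 lower, with BMP2, a marker, at -6.50, BMP6 at -5.87 and SMAD6 at -2.95, while BMP4 was listed at 0 in hypoblast-like cells. SMAD6 was at 0 in both without the cell LB_inner G-12, and BMP2 stood at -2.58 without HB_inner G-14. Of 9 LIF pathway genes 3 were higher and 4 lower, with CISH at 3.55, LIFR at -2.90, OSMR at -2.57 and SOCS3 at -4.90. Without the cell HB_inner G-14, SOCS3 stood at 0.09 and OSMR at -0.78. Within letter G the splits of higher to lower were 3 to 9 of 15 for WNT, 4 to 7 of 12 for Nodal, 4 to 4 of 13 for FGF, 3 to 5 of 12 for BMP and 2 to 5 of 8 for LIF pathway genes, with FGF at percentile 33.4 and BMP at 16.1.

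Metabolic genes were higher about as often as all genes, of which 2522 of 7148 were higher in epiblast-like cells and 1868 lower. Of 22 oxidative phosphorylation genes 8 were higher in epiblast-like cells and 0 lower, with NDUFA1 at 2.06, ATP5G1 at 1.99, NDUFB6 at 1.61 and SDHA at 1.55. ATP5G1 stood at 7.45 without the cell HB_inner G-14 and SDHA at 5.56 without LB_inner G-12. Of 18 glycolysis genes 7 were higher and 4 lower, with PFKM at 2.97, HK1 at 2.73, GPI at 2.46 and SLC16A3 at -3.01, which stood at -0.18 without the cell LB_inner G-11. HK1 stood at 4.25 without HB_inner G-14 and GPI at 6.04 without LB_inner G-12. Within letter G the oxidative phosphorylation and glycolysis splits were 6 to 1 and 5 to 3. Over both letters the list medians of 0.78 and 0.81 stood at percentiles 99.0 and 97.1 of random lists. The glycolysis split turned under both other scalings given below. Over all genes outside the clustering, DPPA5 (9.52), MTHFD1 (7.42), KHDC3L (7.07), NUDT5 (6.96), EXOSC5 (6.67), RPP40 (6.39) and ANAPC4 (6.14) were highest in epiblast-like cells, and UCHL1 was listed at 0 in hypoblast-like cells. PCP4L1 (-9.45), GSC (-8.28), CXCR4 (0.0322 against 263 RPKM), IHH (-7.71), DUSP6, FGF17 (-7.56), GADD45A (-7.53) and TTR (-7.47) were lowest. PCP4L1 stood at -7.51 without the cell HB_inner G-14 and FGF17 at -6.76 without LB_inner G-17. GSC stood at -7.15 and TTR at -6.56 without LB_inner G-11. With 4 hypoblast-like cells, all of letter G, 19.0% of unchanged genes passed 2-fold in simulated groups of this size. The simulated spread was that of letter H hatched blastocyst cells and may not match the spread of these cells. Median-of-ratios size factors on the same cells gave splits of 2 to 7 for Nodal, 2 to 5 for LIF, 5 to 7 for glycolysis and 4 to 1 for oxidative phosphorylation genes, and factors over genes above 0 in all cells 2 to 7, 2 to 4, 6 to 7 and 5 to 1.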

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

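No test of an explanation belongs to the values in this part, and the lineage genes looked at were named before the data were examined. In each group of 4 to 10 cells, the highest and lowest cell was compared with its nearest neighbour by Dixon's criterion, on log2(RPKM + 1) for genes. Of 75 sets of values 16 held a cell far from the others, where chance gives about 3.75 (1 in 20). Genes that are on in few cells give such values readily, so a distant cell is no sign of a fault.

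Hypoblast genes gave 7 of these. GATA4 stood at 9.94 RPKM in the cell EM_inner H-05, where the 4 others were at 0, at 30.9 in EB_inner A-08, where the next cell was at 2.82, and at 309.6 in MB_outer B-03, where the next was at 0.302. SOX17 stood at 0.0941 in LM_outer D-05 and at 0.430 in LM_inner D-04, and PDGFRA at 0.103 in LM_outer D-05, all close to the floor of the table. PDGFRA stood at 14.0 in MB_outer B-02, where the next cell was at 0.517.

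Trophectoderm genes gave 6. CDX2 stood at 7.05 RPKM in EM_outer H-04, at 32.6 in LM_outer D-01 and at 85.2 in MB_outer B-07, where the next cells were at 0.0329, 0.0490 and 1.49. GATA2 stood at 5.34 in EM_inner H-05, where the 4 others were at 0, and at 4.28 in EB_inner G-13, where the next was at 0.431. KRT18 stood at 331 in LM_outer D-10, where the next was at 5.42. The cell EM_inner H-05 was thus the highest of its group for both GATA4 and GATA2.

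The other 3 were SOX2 at 3.54 RPKM in EB_outer A-02, where the next cell was at 0.651, the cell EM_outer H-05 with 7.24 megareads recovered, below the 8.50 megareads of the next, and EM_outer H-04 with 7379 genes at 1 RPKM or more, above the 6817 of the next. For none of the 10 lineage genes did all outer cells lie above all inner cells at one stage and below them at another.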

How the results depend on the processing

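The pseudocounts, the limit of 4 megareads, the early cluster as a substitute, leaving out its late blastocyst cells, its middle blastocyst cells of letter G or each hypoblast-like cell, list counts without markers or, within letter B, without each outer cell, and the factors over genes above 0 in all cells were chosen after the data were seen. The G2/M and stress lists were also read for the late morula without having been planned there. No paired analysis was possible because the cell numbers in the titles name no shared embryo or animal and no result comes from a test. Of 279 recomputed values of 15 counts and shares, 246 stayed within 1.5 times the count or within the share's interval and 33 moved. The cause of a move was not tested unless stated.

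The count of higher trophectoderm markers in outer blastocyst cells (10) lay between 9 and 10 with each cell left out, and the epiblast count (3) stayed at 3. A filter of 20 RPKM gave 6 and 0, since fewer genes are measured, and a size of 1.5-fold gave 5 epiblast markers. Before the cavity, 5 lineage markers were past 2-fold (4 to 6 with each cell left out), 2 at 20 RPKM, and 3 at 3-fold or with a pseudocount of 5. Between the 16-cell stage and the late morula, 6 oocyte genes were lower (3 to 8 with each cell left out, 3 without 16C_inner B-01), 3 under median-of-ratios size factors and 1 at 20 RPKM. The 5 genome activation genes (5 to 7 with each cell left out) became 3 under those factors and 8 with no filter. The 11 matrix and 7 lipoprotein genes lower in epiblast-like cells were 10 to 11 and 6 to 7 with each hypoblast-like cell left out.

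Class shares moved most. Median-of-ratios size factors, 3 clusters and 2000 variable genes left 0 hypoblast-like cells in either stage, so that the comparison with hypoblast-like cells had no value there, nor in letter H. With 3 clusters 73.7% of late blastocyst cells were epiblast-like and 3 naive genes were lower instead of 7. With 2000 variable genes 0 late blastocyst cells were trophectoderm-like. Leaving out the 9 conflicting cells, or counting them as hatched, gave 70% epiblast-like and 0 trophectoderm-like late blastocyst cells. Letter G alone gave 0 epiblast-like and 88.9% trophectoderm-like hatched cells, letter H alone 100% and 0, with 0 hypoblast-like, and 0 late blastocyst cells of letter H fell in any named class, which follows from the letters' classes. At 20 RPKM 6 primed genes were higher instead of 11.

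Named genes turned direction in few settings. This is partly fixed by their choice. Those taken from all genes had to keep their direction by depth-weighted mean and within title letters, and list examples had the largest differences. Under median-of-ratios size factors ATP1B1 (0.31), CDC20 (0.02) and SDHA (0.39) did, and with matched letters AMOT (0.20) and SAV1 (0.03). Between epiblast-like and early cells, 3 clusters turned BMP6 (2.96), COX6C (3.92), DUSP6 (0.59), FGFR2 (0.34), GSC (0.57), IL6ST (2.82), LDHA (1.96), NDUFA4 (2.55), NDUFB3 (3.23), UQCRQ (0.94) and ZNF280A (3.42), 4 clusters COX6C (3.90), IL6ST (2.53), LDHA (0.19), NDUFA4 (2.51), NDUFB3 (3.04) and UQCRQ (0.98), and clustering on markers alone BMP6 (0.67) and SLC2A1 (1.32). Letter G turned BMP4 (-0.05) and COX6C (0.49), and letter H EOMES (-2.31). Against hypoblast-like cells 4 clusters turned FGF4 (-2.51), and BMP4 was at 0 in letter G. Leaving out 1 cell turned KRT19 (-0.36, 16C_outer B-01), LAMA1 (-0.26, MB_outer B-01), SFRP1 (1.90, LB_inner G-17) and SOCS3 (0.09, HB_inner G-14), and took SMAD6 to 0 (LB_inner G-12).

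Scaling moved the all-gene median log2 ratio under median-of-ratios size factors from -0.40 to 0.90 (outer against inner blastocyst), 0.10 to 0.21 (before the cavity), -0.24 to 1.49 (late morula against 16-cell), -0.07 to 0.11 (epiblast-like against early) and 0.21 to -0.45 (epiblast-like against hypoblast-like). Factors over genes above 0 in all cells gave 0.02, 0.17, -0.10, -0.01 and -0.27. Depth limits the late morula, whose cells hold 7 of the 9 below 4 megareads.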

Other observations

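In this part, the correlation between title letters and the test of gene length were set before their results were seen, and the tests of depth, of trophectoderm cells, of the 4 late blastocyst cells and of the trophectoderm-like cells were chosen afterwards. The comparisons in the next paragraphs were also made after the data were seen.

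Between late and hatched blastocyst epiblast-like cells, 5 of 6 amnion and gastrulation genes were at least 2-fold higher in late cells and 1 lower, 5 of 9 BMP genes higher and 2 lower, 7 of 15 primed genes higher and 2 lower, and 6 of 11 WNT genes higher and 1 lower. T averaged 170 RPKM (SD 292) in the 7 late and 5.27 (15.8) in the 9 hatched cells, EOMES 35.1 (65.8) against 0.00243 (0.00728), and the BMP target ID3 468 (564) against 3.78 (5.97). ID1 (4.05 log2 units), MSX2 (3.54) and ID2 (3.03) were also higher in late cells, while LEFTY1 (-6.31) and KHDC3L (-1.23) were lower. ZIC2 averaged 196 (128) against 46.1 (41.1). The late cells all carry letter G and the hatched ones letter H, so stage and letter cannot be told apart.

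Within letter G, the 13 trophectoderm-like cells held more RNA of HAND1, at 468 RPKM (597) against 0.0570 (0.0434) in the 7 epiblast-like cells, and of CLDN4 (7.37 log2 units), CLDN3 (6.48) and LDHA (4.58). Of 15 junction and transport genes 10 were higher and 0 lower, and of 14 G2/M genes 7 were higher and 0 lower, with CCNB1 at 171 (175) against 41.2 (38.3). Over all 6993 measured genes 2384 were higher and 1370 lower. The 13 trophectoderm-like cells are labelled inner. Of these, 8 are hatched and 5 late blastocyst cells whose source name says hatched, while the 7 epiblast-like cells are all late blastocyst. Class and stage therefore overlap in this comparison.

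Markers of other cell types were read in all 95 cells. Of the cumulus markers HSD17B1 reached 5 RPKM in 21 cells, with its highest mean (82.0) in outer middle blastocyst cells, AMHR2 and STAR in 2 and INHA in 1. Of the fibroblast markers COL1A2 reached it in 21 cells (highest mean 78.9, hatched blastocyst), COL1A1 in 4 and THY1 in 3. Of the blood markers CD14 reached it in 9 cells (highest mean 47.5, inner 16-cell), LYZ in 8 and ALAS2 in 1, and the sperm markers PRM1, PRM2, TNP1, TNP2, ODF1 and AKAP4 in 0. The most alike pair of cells, both inner cells of the 16-cell stage, correlated at 0.910 on the log2 scale across genes.

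Cells of letters A, B and D differed from cells of letters G and H across stages. Among inner early and middle blastocyst cells the median difference of A and B from G and H was -0.69 over 6710 genes. Sequencing depth as the whole cause was argued against in middle blastocysts, where 4 inner cells of letter B, each deeper than 3 inner cells of letters G and H, differed from these by a median of 2.78 log2 units (2.78 to 2.91 with each cell left out) over 3435 genes, signed by their direction between 16-cell with late morula and early morula cells. A library or collection set shared by letters may contribute, as the difference of letter A from G and H in early blastocysts correlated across 5453 genes at r 0.575 with that of 16-cell and late morula from early morula cells, which share no cell with it (genes are not independent replicates). Trophectoderm cells among the inner cells of letters A and B may add to it in blastocysts, where the trophectoderm list had a median difference of 2.89 over 9 genes, but such cells are no part of the earlier stages. Gene length stays open, with rho at -0.112 over the 90.1% of genes with a recovered length, between the bounds set, and base composition, shared reads of pseudogenes and developmental stage were not tested.

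The 4 late blastocyst cells of letter H fell in the early cluster, and their source name says hatched. A wrong label on early or middle blastocyst cells stays open. The primed list was higher in the 4 cells than in the 5 early and middle cells of letter H in that cluster by a median of 1.23 log2 units (0.78 to 1.65 with each of the 4 left out), but the 3 middle cells already differed from the 2 early ones by 2.66. With so few cells and no embryo named, wrong labels and a true difference of stage cannot be told apart.

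All 13 trophectoderm-like inner cells carry letter G. The letter without the stage does not set the class, since 11 of 24 late and hatched blastocyst cells of letter G lay outside it. Of these 11, 7 were epiblast-like and 4 hypoblast-like. This was asked after the clusters were seen and only describes the counts. Among hatched blastocyst cells, 8 of 9 of letter G and 0 of 9 of letter H were in the class. A class that follows the letter within a stage therefore stays open. The 5 late blastocyst cells among the 13 may be hatched blastocyst cells, as their source name says. Their mean correlation with the 8 hatched cells was 0.473, against 0.570 within both sets, a difference of -0.0971. No label names the embryos, so a difference between embryos of the same stage could not be set apart and this stays open, as does a wrong position label or a true inner position, neither of which was tested.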
